A study of Mus musculus with 2 samples.

How the data were processed

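Kidney RNA of male mice was measured on 2 Affymetrix whole-transcript expression arrays, 1 for Iah1-WT and 1 for Iah1-KO mice. Per the labels' protocols, the mice ate standard chow until 6 weeks of age and a high-fat diet for the next 12 weeks, were housed singly, and were killed in the early afternoon after 4 hours without food. Per the series description, RNA of 3 mice was pooled for each array. Per the labels' protocols, total RNA was extracted with Trizol and cleaned on a column, and biotin-labelled targets were made from 100 ng.

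The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console 1.3.0, per the submitters' processing notes. RMA subtracts an estimated background, forces the arrays to a common distribution by quantile normalization and summarises the probes of a set on the log2 scale. A change that moves most transcripts the same way would therefore not be visible, and differences of dim probe sets are compressed. The 2 columns had medians of 4.05 (Iah1-WT) and 4.03 (Iah1-KO), and upper quartiles of 6.02 and 6.03. The genome build used to annotate the array is not given in the sources used here, so no coordinates are reported. Probe sequences, scanner intensities and detection calls were not used here.

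The table held 41345 probe sets. GEO's platform annotation gave exactly 1 gene symbol to 23521 of them, several to 1814 and none to 16010. Of the 23521, 23328 had an Entrez number that is in the RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol changed when looked up there. Only probe sets with exactly 1 symbol were assigned to a gene, which left out genes whose probe sets carry several symbols. They covered 22180 genes. For the 1082 genes with more than 1 probe set, the brightest over the 2 arrays was used.

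Everything below was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The difference of a gene is its log2 value in the Iah1-KO pool minus that in the Iah1-WT pool, with no further normalization. Counts and gene lists used the 7671 genes (34.6% of 22180) whose higher value was at least 6 on the log2 scale, the expression floor. A threshold of 2-fold defined the counts. As a description of the spread, a robust SD (median absolute deviation times 1.4826) was taken over the 500 genes nearest in mean expression. Lists of cell type markers (14), and of pathways, locus genes and check genes (25), were fixed before the data were examined. Of their 840 entries, 736 matched a gene (2 through a synonym); the other 104 were not analysed here. The median difference of a list was set against 10000 random lists of the same size, each member replaced by a random gene out of the 200 nearest in mean expression. The middle 98% of the random medians is the random range, and a list was called outside it when its percentile was under 1 or above 99. Lists with fewer than 4 genes at or above the floor were given as values only. On data simulated for the 7671 genes, the list procedure placed 2.4% of unshifted lists of 20 genes outside, and 64.5% of such lists shifted by -0.1.

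With 1 array per genotype no test between genotypes is possible, and no p-value, standard error or SD between replicates is reported; the robust SDs describe the spread over genes on these 2 arrays. The pools average over mice, so the spread between mice is unknown, and the number of arrays limits the precision. Percentiles describe these 2 arrays. Random lists treat genes as independent, whereas genes of one pathway vary together, so real lists scatter more widely than the random range.

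The genes named were chosen by a rule fixed before the data were examined: Iah1, the 14 genes furthest higher and the 14 furthest lower in the Iah1-KO pool, and up to 4 genes with the largest difference from each list described. Predicted genes, Riken clones, small RNAs and olfactory or vomeronasal receptors were left out of the 14. Alternatives were another floor (log2 5, log2 7 or none), centring the differences on their median, a loess correction on mean expression (span 0.3), the mean over all probe sets of a gene, a threshold of 1.5-fold or of 4 local robust SDs, the mean of a list, and random lists without matching. Counts over all probe sets, and one list without its 2 most different members, were added after the data were seen.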

Results

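Kidney expression was compared between mice with a systemic knockout of Iah1 and wild-type mice, both kept for 12 weeks on a high-fat diet. Iah1 encodes a homolog of an isoamyl acetate-hydrolysing esterase. Each genotype was represented by 1 array that carried pooled RNA of 3 males, so the differences below are between 2 pools and have no replicate check. Values are log2 RMA values. The 2 arrays correlated with Pearson's r = 0.990 and Spearman's rho = 0.986 across the 7671 genes at or above the expression floor; genes are not independent replicates. The middle 95% of these genes differed by between -0.30 and 0.35 on the log2 scale, with a median difference of 0.01, and 99.6% differed by less than 1.5-fold.

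The targeted gene was examined first. Iah1 (probe set 17274471, chromosome 12) had a log2 value of 9.09 in the Iah1-WT pool and 3.60 in the Iah1-KO pool. The Iah1-KO value lay below the median of all probe sets on that array, 4.03, and is not shown to be above background. The size of the difference between these values, -5.49, is therefore a lower bound, and it ranked 1 of 7671 genes. The part of the gene that was deleted and the position of the probes within it are not given in the sources used here. Genes listed as lying near Iah1 did not share its difference: 13 of them were at or above the floor, with a median of -0.05 at percentile 10.1 of random lists and 0 members beyond 1.5-fold. Hpcal1 was furthest higher (0.30) and Cpsf3 furthest lower (-0.25), followed by Mboat2 at 0.19 and Cys1 at -0.16.

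Other markers of sex and strain at or above the floor differed little between the pools. The Y-linked genes Kdm5d, Eif2s3y and Uty differed by 0.11, -0.09 and 0.07, and Xist, the X-inactivation transcript of female cells, was at 2.55 and 2.40, below the floor. Of the genes known to differ between inbred strains, 5 were at or above the floor, with a median of -0.01. Nnt, the mitochondrial transhydrogenase that is disrupted in C57BL/6J mice, was at 9.44 in the Iah1-WT and 9.43 in the Iah1-KO pool. Glo1, Cd59a and Ide differed by 0.02, -0.02 and -0.07. H2-Ea, also of this list, was below the floor, at 3.40 and 3.59. With 5 genes, the list cannot show that the 2 pools shared a strain background.

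Few genes besides Iah1 reached a 2-fold difference. Across the 7671 genes, 1 was at least 2-fold higher and 3 were at least 2-fold lower in the Iah1-KO pool. The 3 lower genes were Iah1, Cyp4a14 and the transcribed pseudogene Gm6300 (7.89 in the Iah1-WT and 6.81 in the Iah1-KO pool). The higher one was Gm11127, a predicted protein-coding gene on chromosome 17, at 4.49 in the Iah1-WT and 6.32 in the Iah1-KO pool. Gm11127 and Gm6300 fall outside the naming rule and were chosen after their values were seen. At a threshold of 1.5-fold, 17 genes were higher and 16 lower.

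**Figure D1:**
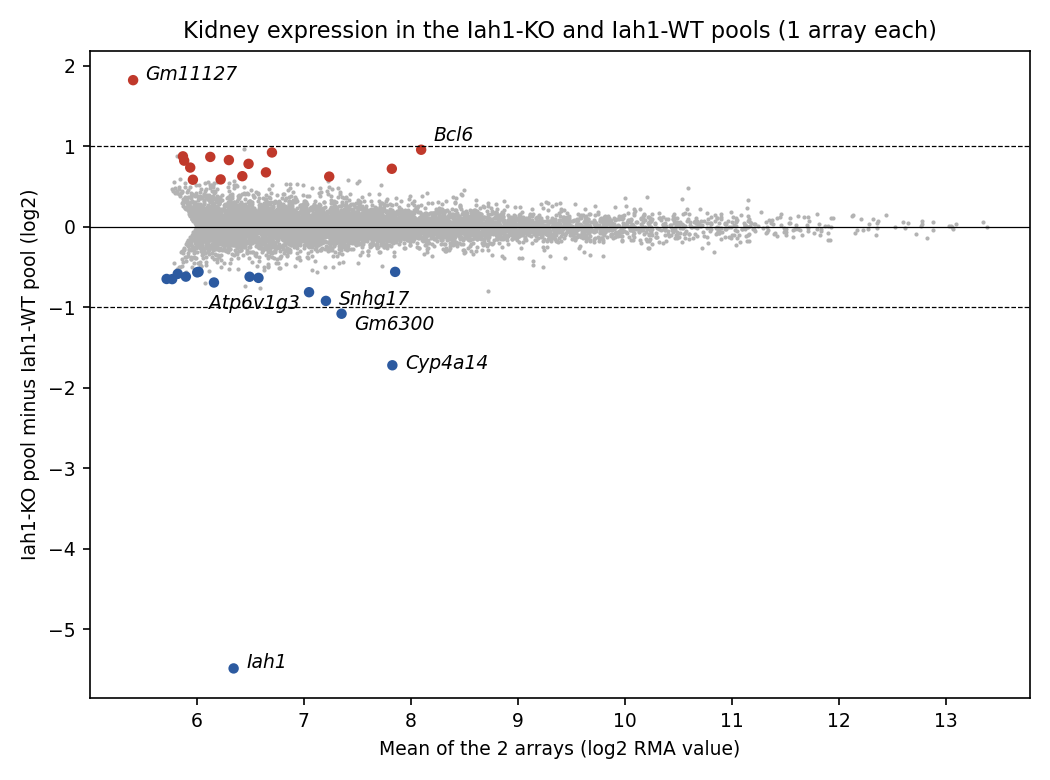
Difference between the Iah1-KO and the Iah1-WT pool (log2, y axis) against the mean log2 RMA value of the 2 arrays (x axis) for the 7671 genes at or above the floor, each a grey point. Coloured points are the named genes (red higher, blue lower in the Iah1-KO pool) and dashed lines mark 2-fold; Iah1, whose plotted difference of -5.49 is a lower bound in size, and Cyp4a14 at -1.72 lie furthest below 0.

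Cyp4a14 (probe set 17428457, chromosome 4), a fatty acid omega-hydroxylase induced by the lipid-sensing receptor PPAR alpha, was 3.30-fold lower in the Iah1-KO pool, at 8.69 in the Iah1-WT and 6.97 in the Iah1-KO pool. The difference of -1.72 compares with a robust SD of 0.12 among genes of similar expression. Its paralog Cyp4a31, named here after its values were seen, was at 11.05 and 10.95. Probe sets that carry the symbols of several genes were not assigned, so the share of signal between Cyp4a paralogs is uncertain. Pdk4, the kinase that inhibits pyruvate dehydrogenase, differed by -0.56.

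These genes belonged to the list of fatty acid oxidation genes and PPAR alpha targets, which as a group was lower in the Iah1-KO pool. Of its 26 genes at or above the floor, 21 lay below 0 and 5 above, and 1 (Cyp4a14) was lower by at least 1.5-fold. The median was -0.10, a 6.93% lower signal, at percentile 0.01 of random lists, whose middle 98% lay between -0.06 and 0.06. Acot1, a cytosolic acyl-CoA thioesterase, differed by -0.39, and Angptl4, a secreted inhibitor of lipoprotein lipase, by -0.36. Without Cyp4a14 and Pdk4 the median of the other 24 genes was -0.10. Proximal tubule markers, which label the cell type that carries out most fatty acid oxidation in the kidney, had a median of 0.05 over 19 genes (percentile 97.1), with Slc22a8 at 0.23, Gatm at -0.20, Keg1 at -0.16 and Acsm2 at 0.15.

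**Figure D2:**
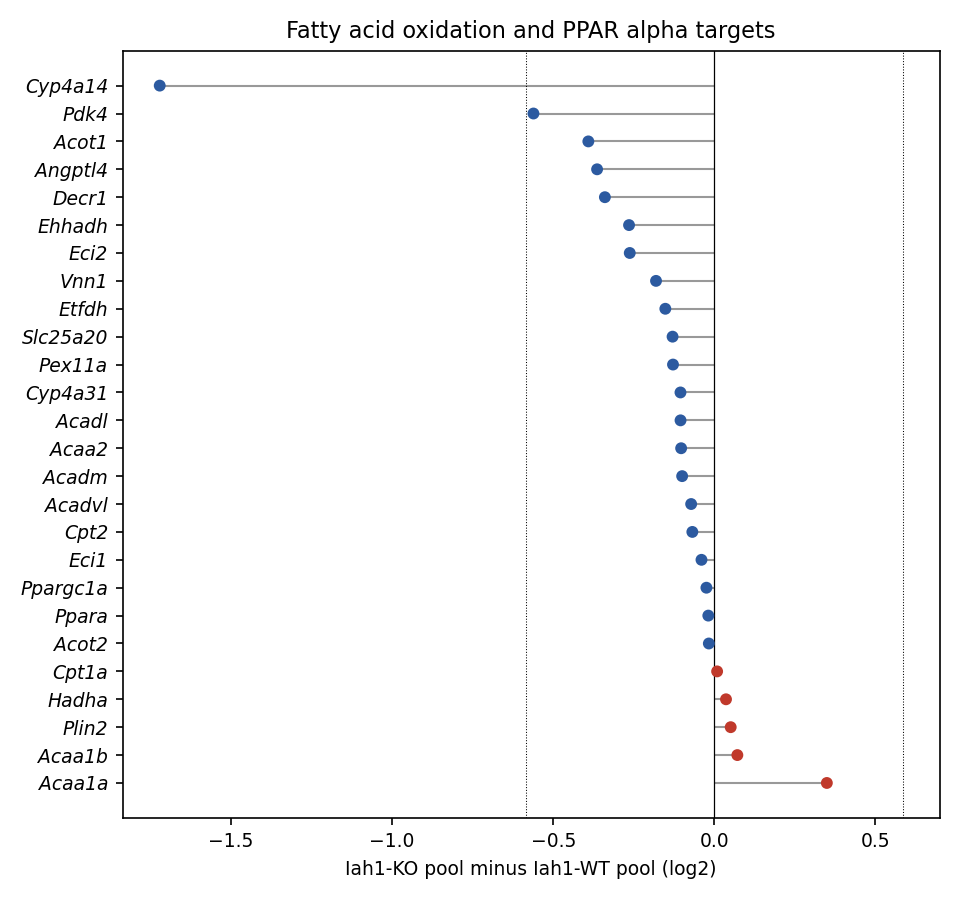
Difference between the Iah1-KO and the Iah1-WT pool (log2, x axis) for each of the 26 fatty acid oxidation genes and PPAR alpha targets at or above the floor (y axis), 1 array per genotype. Blue points are lower (21 genes) and red points higher (5 genes) in the Iah1-KO pool, and dotted lines mark 1.5-fold.

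Other lists of lipid and energy metabolism stayed inside the random range. Fatty acid and triglyceride synthesis had a median of 0.01 over 21 genes. Srebf1, the regulator of fatty acid synthesis, was at 6.16 in the Iah1-WT and 5.78 in the Iah1-KO pool, Mogat1 and the desaturase Fads1 both differed by -0.20, and Elovl6 by 0.14. Cholesterol synthesis genes had a median of 0.01 over 14 genes, with Cyp51 at -0.27, Mvd at -0.25, Msmo1 at 0.24 and Stard4 at -0.16. Esterases and neutral lipases had a median of 0.00 over 18 genes with 0 beyond 1.5-fold. Among them Pnpla7 differed by 0.27, Abhd6 by -0.16, the triglyceride lipase Pnpla2 by 0.15 and Ces2g by -0.13. Glucose production and glycolysis had a median of 0.03 over 20 genes, with Pck2 furthest at 0.28. Nuclear genes of oxidative phosphorylation had a median of 0.00 over 38 genes, all between -0.17 and 0.18.

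Cytochrome P450 and glucuronidation genes differed in both directions, with a median of -0.02 over 23 genes (percentile 19.2). Besides Cyp4a14, Cyp2d9 was lower in the Iah1-KO pool by a difference of -0.56, its family member Cyp2d22 was higher by 0.54 and Ugt3a1 differed by -0.38. Genes that are higher in male kidney had a median of -0.02 over 16 genes, with Gusb, the androgen-induced beta-glucuronidase, at 0.34. Genes higher in female kidney, a list that also holds Cyp4a14, had a median of -0.01 over 6 genes, with Cyp7b1 at -0.25 and Slc7a12 at 0.19.

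Of the 32 lists with a percentile, clock genes had the highest median. Over 14 genes the median was 0.14, a 10.4% higher signal, at percentile 99.96, with 9 genes above 0, 5 below and 0 beyond 1.5-fold. The clock output factors Hlf and Dbp differed by 0.24 and 0.22, the clock repressor Cry2 by 0.23 and Tsc22d3 by 0.22. The 5 below 0, named after their values were seen, were Per3 (-0.15), Per1 (-0.13), Nr1d2 (-0.07), Clock (-0.03) and Nr1d1 (-0.02). The list was therefore not higher throughout. The mean of this list, 0.09, lay inside the random range at percentile 98.2. Heat shock proteins had a median of 0.10 over 13 genes at percentile 98.0, with Chordc1 at 0.32 and Hsph1 and Dnajb1 both at 0.24. Immediate early genes had a median of -0.05 over 9 genes, with Dusp1 at 0.38 and Ccn1 at -0.32. The unfolded protein response list had a median of 0.00 over 16 genes, with Sesn2 at 0.40 and Xbp1 at -0.38.

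Outside the predicted and non-coding name classes, Bcl6 was the gene furthest higher in the Iah1-KO pool. This transcriptional repressor was at 7.62 in the Iah1-WT and 8.57 in the Iah1-KO pool, a 1.94-fold higher value against a robust SD of 0.10 on the log2 scale for its expression. Tmem26 was higher by 0.92, Snai2 by 0.87, Sim1 by 0.78, Zbtb16 by 0.73, Pawr, a pro-apoptotic regulator, by 0.72, Thap4 by 0.68, Prob1 by 0.62, the heparan sulfate sulfatase Sulf2 by 0.59 and Tmem150c by 0.58. The ribosomal protein gene Rpl34 was higher by 0.87 while its list of 20 ribosomal proteins had a median of 0.04; processed pseudogene copies can share its probes. The immunoglobulin variable segment Igh-VS107 was higher by 0.83 in its brighter probe set and differed by -0.42 in the other, so it is uncertain. Snai2, Zbtb16, Sulf2, Tmem150c, Rpl34 and Igh-VS107 reached the floor in the Iah1-KO pool alone. Genes that dim enter through their higher value, which favours large differences. The robust SD near their expression was 0.28 for Snai2, Zbtb16 and Tmem150c, and 0.16 to 0.18 for the others.

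Among the genes furthest lower, Snhg17, a host gene of small nucleolar RNAs, was at 7.67 in the Iah1-WT and 6.74 in the Iah1-KO pool in its brightest probe set, and its other 2 probe sets differed by -0.60 and 0.19. Atp6v1g3, a subunit of the proton pump of collecting duct intercalated cells, was 1.76-fold lower (7.46 and 6.64). Enoph1, an enzyme of the methionine salvage pathway, differed by -0.69, Aldh3b2 by -0.65 and Rgcc by -0.65. Timm8a1, of the mitochondrial import machinery, differed by -0.64 in its brightest probe set, by -0.60 in another and by 0.24 in the third. Ifnl2, an interferon lambda gene with a near-identical paralog, differed by -0.62, Vamp1 by -0.62, Trim41 by -0.59, Pcp4l1 by -0.57 and Wdr20 by -0.56. Enoph1, Aldh3b2, Rgcc, Vamp1, Trim41, Pcp4l1 and Wdr20 reached the floor in the Iah1-WT pool alone. The robust SD near their expression was 0.18 for Enoph1 and 0.27 to 0.28 for the others. Where both of a gene's 2 brightest probe sets were at or above the floor (114 genes), their differences correlated weakly across genes (Pearson's r = 0.18, Spearman's rho = 0.18) and lay a median of 0.11 apart, with a 95th percentile of 0.45.

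Markers of the nephron segments stayed inside the random range. Besides Atp6v1g3, intercalated cell markers had Kit at 0.28, Rhcg at -0.20 and the anion exchanger Slc4a1 at 0.18, and a median of -0.08 over 12 genes (percentile 3.41). Principal cell markers had a median of 0.04 over 10 genes, 5 above and 5 below 0 and 0 beyond 1.5-fold, with Aqp4 at 0.57, Aqp2 at 0.49, Scnn1g at 0.16 and Aqp3 at 0.14. The loop of Henle list had a median of -0.06 over 8 genes, with Cldn10 at -0.24, Kcnj1 at -0.16 and Slc12a1, the bumetanide-sensitive cotransporter, at -0.12. The distal tubule list had a median of 0.04 over 11 genes, with Cnnm2 at 0.48. Renin-angiotensin and blood pressure genes had a median of -0.06 over 12 genes, with the mineralocorticoid receptor gene Nr3c2 at 0.25.

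Endothelial markers were higher in the Iah1-KO pool by a median of 0.10 over 13 genes, at percentile 99.1, with 11 genes above 0 and 0 beyond 1.5-fold. Cdh5, Ehd3, Ptprb and Flt1 differed by 0.24, 0.21, 0.17 and 0.16. Under 7 of the 8 alternative settings the list lay inside the random range, with percentiles down to 97.6. Podocyte markers had a median of 0.06 over 4 genes, and fibroblast, mesangial and smooth muscle markers of -0.01 over 11 genes.

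Immune and injury genes gave mixed values. Lyz2, the lysozyme gene of myeloid cells, and Cx3cr1, a chemokine receptor of resident macrophages, were higher by 0.63 and 0.41, while the other macrophage and dendritic markers Csf1r and H2-Ab1 differed by 0.11 and 0.07; the median of the 7 genes was 0.07 at percentile 84.5. Cxcl9, a chemokine induced by interferon gamma, was at 5.47 in the Iah1-WT and 6.29 in the Iah1-KO pool, whereas interferon-stimulated genes had a median of -0.05 over 14 genes, with Ddx58 at -0.26 and Gbp7 at -0.23. Other members of the list of inflammatory cytokines and chemokines at or above the floor differed by up to 0.16, as Nfkbia did at -0.16. The tubular injury list had a median of 0.08 over 6 genes, with Il34 at 0.21, and extracellular matrix genes of 0.01 over 12 genes, with Col6a1 at -0.32 and Tgfb1 at -0.22. NRF2 targets had a median of 0.05 over 21 genes, with Gsta3 at -0.39 and Hmox1 at 0.36.

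Adrenal and urothelial lists, for tissue that dissection could carry along, had 0 genes at or above the floor. Adipocyte markers had a median of 0.00 over 5 genes, with Cd36 at -0.12 and Fabp4 at -0.07. The other 10, such as Adipoq, Plin1 and Lep, lay below the floor, and with no floor the median was -0.12. The 5 genes therefore say little about fat carried along. The red blood cell list had 2 genes at or above the floor, Bpgm at -0.28 and Slc25a37 at -0.08, and the lymphocyte list had 1, Ighm at 0.23. Of the cell cycle genes, 3 were at or above the floor, with Ccnd1 at 0.29, Pcna at -0.12 and Tyms at 0.00. Genes encoded in mitochondrial DNA were not analysed here. In all, 3 of the 32 lists with a percentile lay outside the random range, against 0.64 for lists of independent genes.

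**Figure D3:**
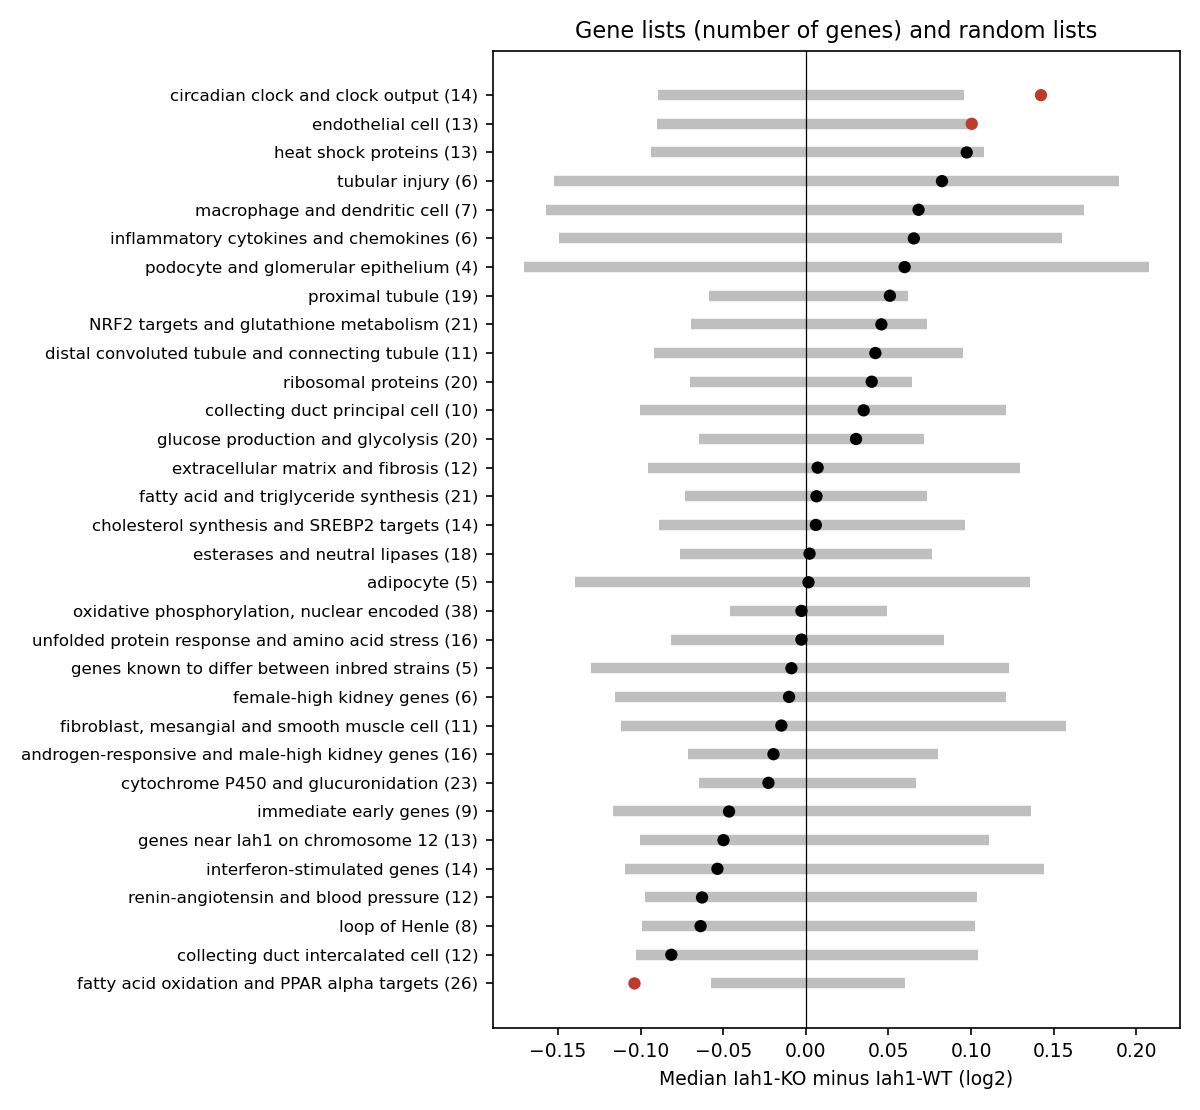
Median difference between the Iah1-KO and the Iah1-WT pool (log2, x axis) for the 32 gene lists with at least 4 genes at or above the floor (y axis, number of genes in brackets). Points are list medians (red where the percentile is under 1 or above 99) and grey bars the middle 98% of 10000 random lists matched on expression; fatty acid oxidation and PPAR alpha targets at -0.10, clock genes at 0.14 and, narrowly, endothelial markers at 0.10 lie beyond their bars.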

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

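Probe sets without a gene symbol belong to no comparison above, and the tests on them were chosen after the result was seen. Of the 2993 probe sets at or above the floor without exactly 1 symbol (2493 with none), 45 were at least 2-fold higher and 34 at least 2-fold lower in the Iah1-KO pool. In 8 of them, all without a symbol, the Iah1-KO value exceeded the Iah1-WT value by more than in any named gene at or above the floor (highest, 1.82 for Gm11127). In 5 of the 8 the Iah1-WT value lay below that array's median of 4.05 and is not shown to be above background. Their differences would be lower bounds only if the Iah1-KO signal is real, which 1 array cannot show. The differences were 4.58, 4.54 and 4.33 on the log2 scale for probe sets 17549080, 17549054 and 17549096, at 7.57, 7.51 and 7.19 in the Iah1-KO pool. They were 2.51 for 17257066 and 2.23 for 17405671. The other 3 were higher by 2.17 (17204729), 1.97 (17467384) and 1.88 (17538757).

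The first 3 of these probe sets stand together in the table, and noise of unnamed, dim probe sets was tested as a cause. Of the 16010 unnamed probe sets 4 had a difference of at least 4 and 0 had one of at most -4, and 3 of the 4 lay within 25 places of each other in the order of the unnamed probe sets. Random placement of 4 probe sets gave such a cluster in 0 of 10000 draws, but the bound of 4 and the distance of 25 were set after the cluster had been seen, so the draws decide nothing. The robust SD of the differences was 0.23 over the 2993 probe sets, and those other than the 3 reached from -2.64 to 2.51. Over all other probe sets without a symbol, dim ones included, the differences reached from -3.39 to 4.03, so noise is not excluded. RNA of a sequence that the knockout brought in, such as a marker gene of a targeting construct, may account for these 3 probe sets, and so may a control RNA added to one sample. These explanations cannot be told apart, because neither the names nor the sequences of the probes are known here and each genotype has 1 array.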

How the results depend on the processing

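Counts over all probe sets and the list without Cyp4a14 and Pdk4 (median -0.10) were chosen after the data were seen. The counts of 2-fold differences (1 higher, 3 lower) depend on the floor, which sets how many dim genes are counted. They were 6 higher and 6 lower with a floor of log2 5, and 0 higher with a floor of log2 7. With no floor they were 19 higher and 21 lower. Dim genes also scattered more, with a robust SD of 0.28 near the expression of Snai2 and 0.10 near that of Bcl6. A threshold of 1.5-fold gave 17 and 16, and 4 local robust SDs gave 15 and 20. Counting all probe sets, named or not, gave 46 and 37. The number of lists outside the random range (3) was between 2 and 4 in every alternative. Fatty acid oxidation and PPAR alpha targets lay outside in each of them, with values between -0.18 (the mean) and -0.10. Clock genes lay outside except for the list mean (0.09, percentile 98.2). Endothelial markers lay outside only as deposited or centred. Heat shock proteins did so only with a floor of log2 5 or the mean over probe sets. The list mean put 4 lists outside, 3 of which were inside by the median. Of these 3, the female-high and the cytochrome P450 list both hold Cyp4a14 (-1.72), and the macrophage list holds Lyz2 (0.63). A single far member moves a mean more than a median, but the cause was not tested. Of 183 alternative list values in which members or their differences changed, 26 moved by more than the spread of random medians. Among the 14 genes furthest higher and the 14 furthest lower, 3 had several probe sets. All 3 moved by more than the robust SD of all genes (0.13) in the mean of their probe sets. They moved to -0.44 (Snhg17), 0.20 (Igh-VS107) and -0.33 (Timm8a1). Genes named only as members of a list, such as Col6a1 and Ighm, were not followed singly. No paired analysis was possible because each genotype has 1 array, and for the same reason no replicate could be left out. Signal over background was not known here, which limits what dim probe sets can show.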

Other observations

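The tests of a bias shared by genes of like expression, of proximal tubule markers and of the neighbours of Iah1 in this part were chosen after the results were seen. Below the expression floor, and so outside the comparisons above, lie some kidney and immune genes that were picked after their values were seen. Cyp27b1, the renal enzyme that makes active vitamin D, was at 5.91 in the Iah1-WT and 4.87 in the Iah1-KO pool. The macrophage marker Adgre1 was at 5.10 and 4.37, and the dendritic cell integrin Itgax at 4.70 and 5.47. Small nucleolar RNA symbols (57 at or above the floor) had a median of -0.03, with 1 higher and 2 lower by at least 1.5-fold, and 29 microRNA symbols had a median of 0.02.

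The lower level of fatty acid oxidation genes and PPAR alpha targets in the Iah1-KO pool was set against technical explanations. A bias shared by genes of like expression would also shift random lists matched on expression. Those lists had a median of -0.002, so genes of like expression were not lower as a whole. The percentile of 0.01 among them is the value that singled out this list and is no further test. A smooth bias along mean expression would be removed by the loess correction, but this moved the median by just 0.002, to -0.10. What the correction shows is the small size of the fitted trend at these genes. The corrected median still lay below the middle 99% of random lists, -0.065 to 0.066. The list had been picked for lying outside matched lists, so this comparison is no further test of such a bias. A smaller share of proximal tubule cells would lower their markers alike, but those had a median of 0.051, with a bootstrap 95% interval over genes of -0.06 to 0.09 that stays above the list's median of -0.10. A difference between the pools unrelated to genotype, such as feeding state or single mice, cannot be told apart from an effect of the knockout with 1 array per genotype.

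Clock genes were higher in the Iah1-KO pool by a median of 0.14, and a difference in the clock phase of the 2 pools may be a candidate explanation. Genes that peak in opposite phases would then move apart. The median of morning-phase genes was 0.15 and of evening-phase genes 0.10, which is 0.050 apart and within the bound of 0.1 set beforehand against a phase difference. That bound was unsuited to these arrays, since just 1 of the 5 morning-phase genes was at or above the floor (8 of the 9 evening-phase genes), so the explanation stays open.

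A local effect of the targeting, or DNA of another strain around the locus, would make the neighbours of Iah1 differ more than other genes. The 30 genes at or above the floor on each side had a median absolute difference of 0.10, at percentile 71.2 of random lists. This argues against an effect on most of these genes, but a median cannot show one on single genes or a minority. It weighs all 60 alike, so it says little about the few nearest to Iah1. Of the 60 genes 1 differed by at least 1.5-fold, the predicted gene Gm6943 (-0.76), which was named after its value was seen. It lay at place -4 from Iah1 among these genes. The nearest on either side, Cpsf3 and Adam17, differed by -0.25 and 0.02. Between Cpsf3 and Gm6943 lay Itgb1bp1 (0.15) and Asap2 (0.05). Beyond Gm6943 came Gm9222 (0.40) and Hpcal1 (0.30), and Trib2 at place -10 differed by -0.50. These too were named after their values were seen, and whether they reflect a local effect was not tested.

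Bcl6 and Zbtb16 respond to glucocorticoids in several tissues, so a stronger glucocorticoid response in the Iah1-KO pool may be a candidate explanation for their higher values. The other glucocorticoid-induced genes (13 at or above the floor) were listed before their median was computed, but after values of some members, such as Dusp1 and Per1, had been seen in other lists. They had a median of 0.10 at percentile 98.0, between the bounds set beforehand, so the test does not decide. Members named after their values were seen are Dusp1 and Fkbp5, at 0.38 and 0.31, and Per1 and Nfkbia, at -0.13 and -0.16.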
